A study of Mus musculus with 8 samples.

How the data were processed

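RNA was measured on 8 Affymetrix expression arrays from mouse embryonic fibroblasts of the C57BL/6 strain. The cells lacked Stat5, and a STAT5 mutant had been returned to them by retrovirus, per the labels. The mutant was either EA, described in the labels as a change of the binding domain from EE to AA, or YF, described as Y694F. Cells of each mutant had received growth hormone for 120 minutes or no stimulation. This gave 4 groups of 2 arrays, and the series text calls the 2 arrays of a group biological duplicates. Each array was assigned to its group and replicate number from its own label.

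Total RNA had been extracted with TRIzol and labelled with biotin, per the labels' protocols. The table held log2 expression values per probe set, as deposited by the authors, with 1 column per array. The submitters' processing notes name GCOS, the Affymetrix scanner software, and RMA, robust multi-array averaging, without versions, and their order and settings are not given in the sources used here. The deposited log2 values had medians of 2.85 to 2.94 over the 8 arrays, had 75th percentiles of 9.04 to 9.14 and a maximum of 15.2 on every array, so no further normalization was applied. The values formed a dense low group and a broad higher one. Of the tested probe sets, 24773 (55.0%) had a mean below 4 over the 8 arrays, and this low group is referred to by that bound. No detection calls were used, and the scale of a value inside the low group is unknown, so the size of a fold with a side there is uncertain, and such a fold is named as such. A comparison has such a side where the mean of any of its groups lay below the bound. The number of arrays limits the precision.

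The table held 45101 probe sets, and 64 control probe sets were left out. Of the remaining 45037, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none there. No gene was named from a probe set with several symbols. Symbols were checked through gene identifiers against the RefSeq gene table of GRCm38.p6, which matched 34741 of the 1-symbol probe sets and changed 0 symbols, and the named probe sets covered 18193 genes. The gene table was used for names alone, and positions in the genome are not analysed here.

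Differences were tested with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes, without a trend or robust option, in a model of 4 group means over all 8 arrays. This left 4 residual degrees of freedom, and the prior had 1.26. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 45037 probe sets, and an adjusted p under 0.05 was called passing. There were 7 contrasts: growth hormone against none in EA cells, the same in YF cells, the difference of these responses, EA against YF without hormone, EA against YF with hormone, and the averages of the hormone effect over mutants and of the mutant effect over treatments. Every log2 change is the first-named side minus the second, SE is its moderated standard error, and n is 2 arrays per group. Any adjusted p printed for a gene comes from this limma model. Each probe set has 1 spread shared by the 4 groups. Probe sets inside the low group could have a small SE, such as 0.03 for Socs1 with hormone in EA cells, though not always (Saa3, 0.49). Where some groups lie there, the SE and p of a call may thus be too small.

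The genes named in the text followed a rule fixed before the data were examined. It took Stat5a and Stat5b, up to 10 genes with the largest rise and 10 with the largest fall among passing 1-symbol probe sets whose arrays did not overlap between the sides, every measured member of the STAT5 target list in the hormone comparisons, and up to 4 members of each other list. Genes named outside the rule are identified as such. There were 26 gene lists with 588 entries, also fixed beforehand, of which 540 were measured by a 1-symbol probe set. A gene was represented in its list by the probe set with the highest mean. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with a correlation estimated from the residuals and with fry. The correlation estimate rests on the 4 residual degrees of freedom, so a list may miss the threshold with it for lack of power. For each list, the number of members passing over all probe sets stands beside the number passing when adjusted over the list alone.

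The code was tested on simulated data before it was run. In each simulated comparison 50 probe sets were changed at each of 4 sizes among 45037. The changed ones were drawn only from probe sets of middle level, with means above the low group, and each had the same spread in all groups. The recovery therefore does not cover probe sets in the low group. For the hormone response in EA cells, 20, 38, 46 and 47 of 50 were recovered at log2 changes of 1, 2, 3 and 4, with 12 false calls among 163. For the response in YF cells the numbers were 19, 32, 42 and 46, with 8 false calls among 147. For EA against YF they were 20, 35, 45 and 50 without hormone, with 9 false calls among 159, and 20, 33, 46 and 47 with hormone, with 16 among 162. A simulated list raised by a known amount was called by camera with an adjusted p of 4.3e-25, and 0 of 200 unchanged lists were called. The simulated genes were drawn independently, so this does not test the preset correlation on genes that vary together. Those of the simulated lists also had means above the low group.

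Alternatives tried were quantile normalization, centring each array on its median, 2 filters on dim probe sets (a mean above the median or in the upper quartile of all means), eBayes with trend and robust, a replicate block, a fit on the compared arrays alone, each array left out in turn, the list tests with an estimated correlation and with the mean of all probe sets of a gene. A crossed pairing of the EA replicate numbers was added after seeing the data. A change of pseudocount, planned for linear values, was not run because the values were already on the log2 scale. The replicate numbers were not used as pairs, since no label ties a number to a shared culture or day.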

Results

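Gene expression was profiled on 8 arrays of Stat5-null mouse embryonic fibroblasts that carried 1 of 2 STAT5 mutants. STAT5 is a transcription factor that is phosphorylated on a tyrosine after the growth hormone receptor activates JAK2, and it then drives genes such as Socs2 and Cish. The YF mutant has that tyrosine replaced (Y694F), and the EA mutant is described in the labels as altered in its binding domain. Each mutant was measured without stimulation and after 120 minutes of growth hormone, with 2 arrays in each of the 4 groups. The values are log2 expression values per probe set, and 45037 probe sets were tested.

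The 2 arrays of a group correlated at 0.996 to 0.998 over probe sets, which are not independent replicates. The first principal component, with 73.7% of the variance, separated the EA arrays (-62.4 to -58.0) from the YF arrays (58.8 to 62.1). YF with hormone replicate 1 stood apart from the other YF arrays on the second component, which held 12% of the variance. Its score was -50.9, against -3.04 for replicate 2 of its group and 22.6 and 30.5 for the unstimulated YF arrays. The replicate differences had an SD of 0.336 in YF with hormone, against 0.230 to 0.291 in the other groups.

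Stat5a RNA was lower in EA than in YF cells. The brightest Stat5a probe set had means of 5.10 (SD 0.37, n = 2) in EA cells and 7.88 (SD 0.09, n = 2) in YF cells without hormone, a difference of -2.79 (SE 0.32, limma adjusted p = 0.0071). With hormone the means were 4.57 and 8.19, a difference of -3.62 (SE 0.32, adjusted p = 0.0036), and averaged over treatments the difference was -3.20 (SE 0.22, adjusted p = 0.00094). Hormone gave a Stat5a change of -0.52 in EA (SE 0.32, adjusted p = 0.87) and of 0.31 in YF (SE 0.32, adjusted p = 0.57), neither of which passed. The other Stat5a probe set and both Stat5b probe sets lay at 1.89 to 2.47 in all groups, inside the low group. Which part of the transcript or of the introduced construct each probe set covers was not analysed here, so these values do not check the null background. Ghr, the growth hormone receptor, was abundant in all groups, at 13.71 in EA and 13.98 in YF without hormone, with an average difference of -0.27 (SE 0.03, adjusted p = 0.0042).

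The first comparison asks how cells with the EA mutant respond to growth hormone. Socs2, a feedback inhibitor of cytokine signalling, rose from 2.44 to 7.96 on 1 probe set, a log2 change of 5.51 (SE 0.16, n = 2 per group, adjusted p = 0.0034) from a level in the low group. The brightest Socs2 probe set rose from 6.46 to 11.31, by 4.84 (SE 0.34, adjusted p = 0.029), while 4 further Socs2 probe sets lay in the low group with and without hormone. Bcl6, a transcriptional repressor, fell from 12.41 to 10.59 on its brightest probe set, a change of -1.82 (SE 0.07, adjusted p = 0.0047). The chemokine genes Ccl2 and Ccl20 rose by 6.77 (SE 0.47, adjusted p = 0.029) and 5.83 (SE 0.03, adjusted p = 2.3e-06, from the low group). Further genes with the largest rises were Ccl7 (5.34), Cxcl5 (5.06), Cxcl10 (4.02, from the low group), Cxcl1 (3.93), Tnfaip3 (3.71), Icosl (3.13) and Steap4 (2.97), the last 2 also from the low group. The largest falls were in Fgf18, a fibroblast growth factor (-2.91, SE 0.19), Oaz3 (-1.88), Hs3st3b1 (-1.87), Trib3 (-1.85) and Chac1 (-1.82), followed by Opn1sw, Tmem229b, Spa17 and Slc22a4 (-1.22 to -0.86). Of these, Oaz3, Hs3st3b1, Opn1sw, Tmem229b and Slc22a4 had a side in the low group, and Opn1sw lay there with and without hormone. A brighter Tmem229b probe set gave -0.17 (SE 0.22, adjusted p = 0.87). A second Trib3 probe set gave -1.88 (SE 0.17, adjusted p = 0.052) and just missed the threshold.

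In total 61 probe sets passed in EA cells, 42 higher and 19 lower with hormone, covering 30 and 16 genes, and 2529 had an unadjusted p under 0.05. Of the 61, 9 lay in the low group with and without hormone. Centring each array on its median gave 23 higher and 22 lower. More were lower than higher without EA replicate 1 (15 higher and 32 lower) and without EA replicate 2 (16 and 25). The count was 9 without either of the unstimulated YF arrays, 21 without either YF array with hormone, 15 with the replicate number as a block and 4 in a fit of the 4 EA arrays alone, where fewer arrays estimate the spread.

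Among the gene groups, the cytokine, chemokine and NF-kB target list rose in EA cells. Of its 22 measured members, 7 passed higher and 0 lower (15 higher and 0 lower adjusted over the list alone), with a median log2 change of 1.15 (camera adjusted p = 4.7e-26, adjusted p = 0.050 with an estimated correlation, just missing the threshold). The members were Ccl2, Ccl7, Cxcl5, Cxcl1, Tnfaip3, Nfkbia (1.17, SE 0.06) and Birc3 (1.05, SE 0.08). The unfolded protein response list passed in the lower direction, with 0 of 20 higher and 2 lower (0 and 4 adjusted over the list alone), at a camera adjusted p of 0.00013 (adjusted p = 0.14 with an estimated correlation). Its median was -0.04 and its mean -0.28, and 7 of the 20 members had values above 0. The 2 members were Trib3, a pseudokinase, and Chac1, a glutathione-degrading enzyme, both known as targets of the stress factor ATF4. The immediate early list had a median of -0.18 and a camera adjusted p of 0.0058 in the lower direction (adjusted p = 0.79 with an estimated correlation). None of its 33 members passed in limma over all probe sets (3 higher and 4 lower adjusted over the list alone), with 3 higher and 7 lower at an unadjusted p under 0.05. Its largest changes were -2.34 for Fos (SE 0.28, adjusted p = 0.11) and 1.79 for Nr4a3 (SE 0.35, adjusted p = 0.34).

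STAT5 target genes did not pass as a group in EA cells. Of 19 measured members, Socs2 passed higher and Bcl6 lower (2 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.72. Cish, another feedback inhibitor, went from 4.68 to 6.83, a change of 2.15 (SE 0.21, adjusted p = 0.064) that missed the threshold. Igf1 had a value of 1.18 (SE 0.44, adjusted p = 0.83), Myc -0.83 (SE 0.55, adjusted p = 0.87) and Pim1 0.37 (SE 0.12, adjusted p = 0.66). For the other 13 members, values lay between -0.27 for Bcl2l11 and 0.09 for Cdkn2b, and none passed. Between these lay Socs3, Ccnd1, Ccnd2, Bcl2l1, Mcl1, Cdkn1a and Nox4, and inside the low group Socs1, Il2ra, Igfals and Osm.

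**Figure D1:**
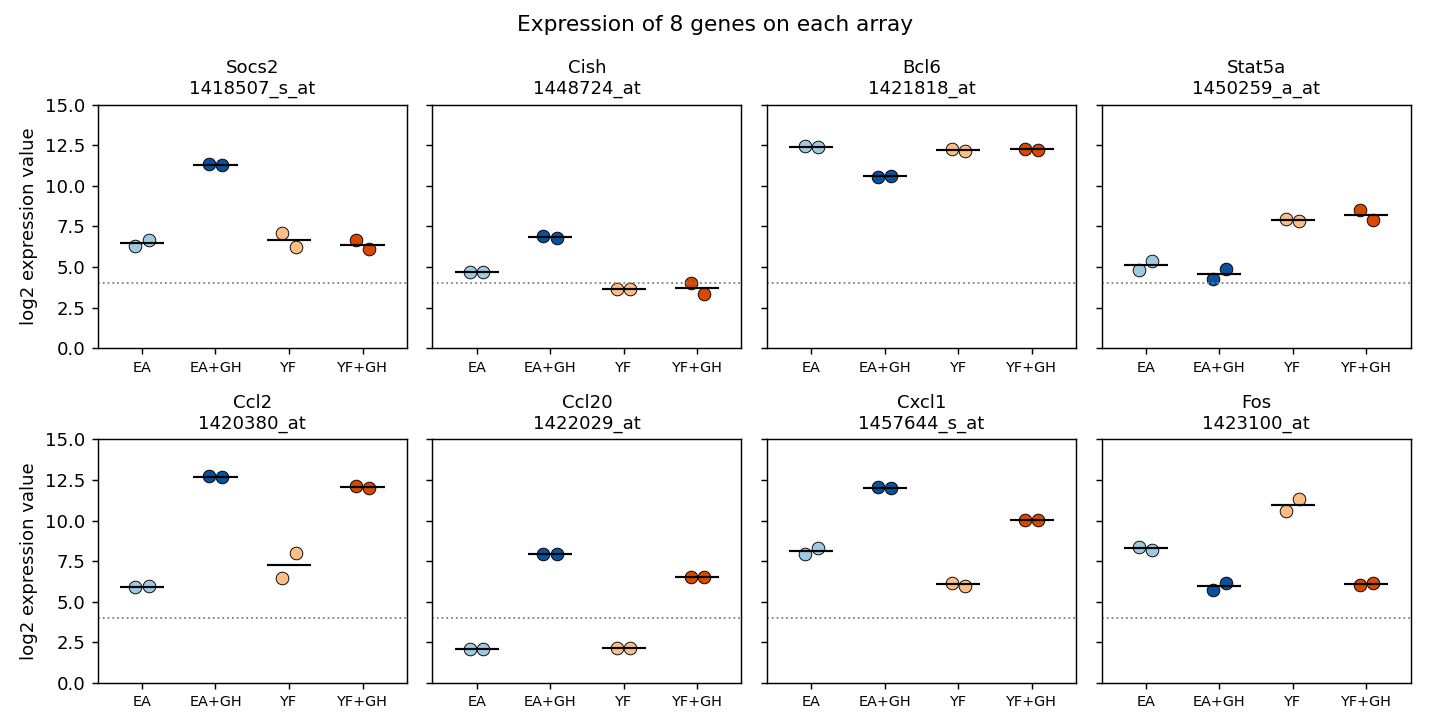
Log2 expression values (vertical axis) of 8 genes, 1 panel per gene and probe set, on the 2 arrays of each group, where points are single arrays, horizontal bars are group means, and the dotted line at 4 bounds the low group. Socs2 stood at 11.31 in EA with hormone against 6.37 in YF with hormone, Bcl6 at 10.59 against 12.24, and Ccl2 at 12.70 against 12.07.

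The second comparison asks the same of cells with the YF mutant. Chemokine genes again had the largest rises, with Ccl20 up by 4.39 (SE 0.03, n = 2 per group, adjusted p = 1e-05) and Cxcl10 up by 4.12 (SE 0.27, adjusted p = 0.022), both from the low group. Bcl3, an NF-kB cofactor, rose from 5.06 to 9.10, by 4.05 (SE 0.21, adjusted p = 0.013). Cxcl1 rose by 3.98, Cxcl2 by 3.80 (from the low group) and Ccl7 by 3.78. Nfkbia, the NF-kB inhibitor, rose by 3.19 on its most responsive probe set (SE 0.21, adjusted p = 0.022) and by 1.25 on its brightest probe set (SE 0.06, adjusted p = 0.0095). Zc3h12a (2.78), Tut4 (1.93), both from the low group, and Lcat (1.58) completed the 10 largest rises. Ccl2 had a value of 4.82 (SE 0.47, adjusted p = 0.051), just short of the threshold. Fos, an immediate early transcription factor, fell from 10.95 to 6.08, a change of -4.87 (SE 0.28, adjusted p = 0.019). Arsb (-2.55, into the low group), Trib3 (-1.85, on another probe set than in EA cells), Rhpn2 (-1.71, into the low group), Alx1 (-1.41), Ankrd1 (-1.30) and Egr1 (-1.01) also fell. Fndc3c1, Specc1 and Klhl41 fell by 1.01, 0.98 and 0.91, with Specc1 ending in the low group. Brighter probe sets of Arsb (-0.06 and 0.35), Specc1 (-0.04 and 0.03) and Tut4 (-0.59) did not pass, with adjusted p of 0.38 to 0.88. Other probe sets of Ankrd1 (-0.85, SE 0.23, adjusted p = 0.30) and Trib3 (-1.46, SE 0.14, adjusted p = 0.050) also did not pass, so the calls of these genes were not shared by all of their probe sets.

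In YF cells 81 probe sets passed, 58 higher and 23 lower, covering 39 and 18 genes, and 5114 had an unadjusted p under 0.05. Of the 81, 13 lay in the low group with and without hormone. Because 1 array of this contrast stood apart (YF with hormone replicate 1, score -50.9 on the second component), the count was also taken without it, giving 99, and without its partner, giving 675. It was 8 without either unstimulated EA array, 9 without either EA array with hormone, 21 with a replicate block and 1 in a fit of the 4 YF arrays alone. It was 40 without YF replicate 1 and 15 without YF replicate 2, with 16 higher and 24 lower in the former and 7 and 8 in the latter, so that the larger share was then lower.

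Of the 22 genes of the cytokine, chemokine and NF-kB target list, 5 passed higher and 0 lower in YF cells (13 higher and 1 lower adjusted over the list alone). These were Cxcl2, Ccl7, Cxcl1, Nfkbia and Birc3 (1.06, SE 0.08). The list's median was 1.15 and its camera adjusted p 3.7e-11 (adjusted p = 0.24 with an estimated correlation). The immediate early list fell, with 0 higher and 2 lower of 33, Fos and Egr1 (3 higher and 12 lower adjusted over the list alone), a median of -0.29 and a camera adjusted p of 0.0036 (adjusted p = 0.70 with an estimated correlation). Ier2 and Nr4a1 had values of -2.17 (SE 0.48, adjusted p = 0.24) and -2.05 (SE 0.43, adjusted p = 0.21), the latter ending in the low group. None of the 19 STAT5 target genes passed in limma in YF cells, over all probe sets or adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.59, higher in direction, as is the median of 0.02, with a mean of -0.01). Socs2 had a value of -0.30 on its brightest probe set (SE 0.34, adjusted p = 0.59, 95% interval -1.15 to 0.55) and of 0.40 on the one that lay in the low group with and without hormone (SE 0.16, adjusted p = 0.45). Cish had 0.04 (SE 0.21, adjusted p = 0.90), inside the low group, and Bcl6 0.02 (SE 0.07, adjusted p = 0.80). Values were -0.60 for Socs3 (SE 0.18, adjusted p = 0.33), -0.45 for Bcl2l11, -0.33 for Nox4, 0.33 for both Pim1 and Myc, 0.26 for Igf1 and 0.23 for Cdkn2b. For Mcl1, Ccnd1, Bcl2l1, Cdkn1a and Ccnd2, and for Socs1, Il2ra, Igfals and Osm inside the low group, they lay between -0.06 and 0.16. These list values share the array that stood apart (score -50.9).

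**Figure D2:**
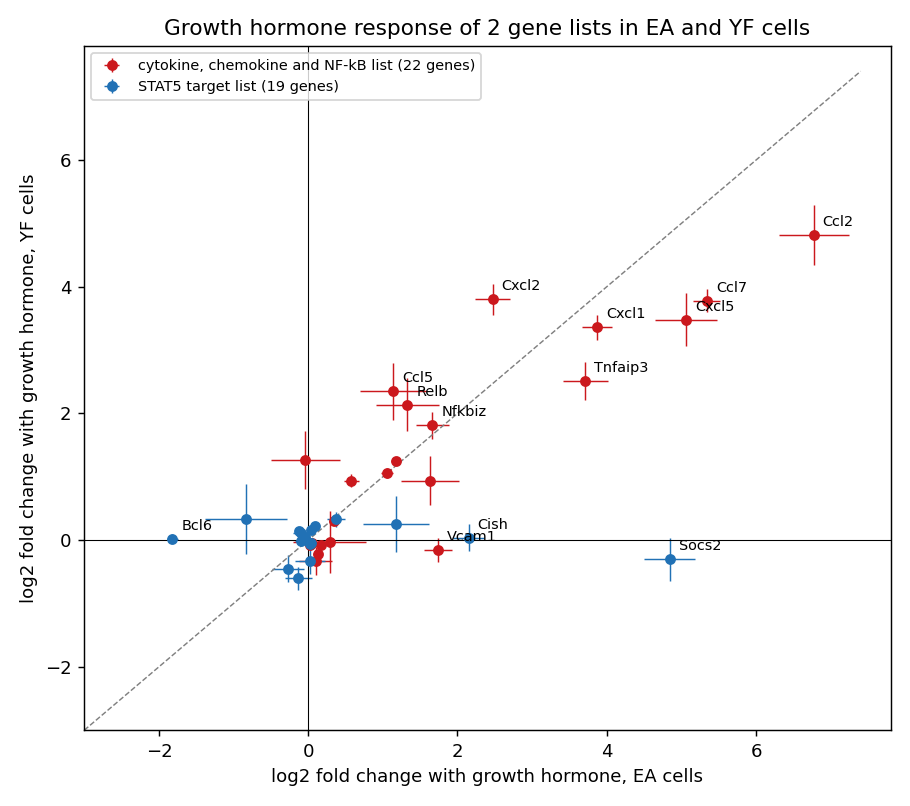
Log2 change with growth hormone in EA cells (horizontal axis) against that in YF cells (vertical axis) for the 22 cytokine, chemokine and NF-kB target genes (red) and the 19 STAT5 target genes (blue), where bars are 1 SE of the model with 2 arrays per group, the dashed line marks equal changes, and each gene is shown by its brightest probe set. Ccl7 lay at 5.34 and 3.78, and Socs2 at 4.84 and -0.30.

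The genes that passed in EA cells were compared with those that passed in YF cells, which share no arrays but 1 estimate of each probe set's spread over all 8 arrays, so the calls of both are not independent. There were 16 probe sets that passed higher in both, and they included Birc3, Ccl20, Ccl7, Cxcl1, Cxcl10, Nfkbia, Nipal1, Tlr2 and Trim47. In limma 0 probe sets passed lower in both, of 19 and 23, and 0 passed in opposite directions, but Trib3 passed lower in both mutants on different probe sets, with the other probe set just short of the threshold in each (adjusted p = 0.052 in EA and 0.050 in YF). Over all 45037 probe sets the 2 responses had a Pearson correlation of 0.0186 and a Spearman correlation of -0.219, and over the 20264 above the low group 0.0688 and -0.0900. Probe sets are not independent replicates, so no p is given. The shared number was 3 without either EA array with hormone, 5 without either unstimulated EA array, 5 and 4 without YF replicate 1 and 2, and 8 with a replicate block.

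The test of the difference between the 2 responses asks which genes respond differently in EA and YF cells. It called 9 probe sets, 4 with a higher and 5 with a lower change in EA, and 4385 had an unadjusted p under 0.05. Socs2 responded more in EA cells, by 5.11 on the probe set that started in the low group (SE 0.23, adjusted p = 0.025, 95% interval 4.53 to 5.70), with an equally large difference of 5.15 on the brightest that did not pass (SE 0.47, adjusted p = 0.10). Bcl6 responded in the lower direction in EA relative to YF, with a difference of -1.85 (SE 0.09, adjusted p = 0.025), although its second probe set, in the low group, gave -1.17 (SE 0.66, adjusted p = 0.45). Ch25h, cholesterol 25-hydroxylase, went from 6.06 to 8.22 in EA and from 6.74 to 7.08 in YF, a difference of 1.82 (SE 0.07, adjusted p = 0.025), and for Ccl20 the difference was 1.44 (SE 0.05, adjusted p = 0.022). Dmp1 (0.88), Opn1sw (-1.17), Gda (-1.16), Cdca2 (-1.05) and Elf2 (-1.04) made up the 9, and apart from Elf2 these had a side in the low group. Dmp1, Gda and Opn1sw lay in the low group in every group of arrays. Brighter probe sets of Dmp1 (-0.57 and 0.09), Gda (-0.21), Cdca2 (-0.76, SE 0.23) and Elf2 (0.07) did not pass (adjusted p of 0.45 to 0.88). Cish had a difference of 2.11 (SE 0.30, adjusted p = 0.20, with the YF side in the low group), Fos 2.53 (SE 0.40, adjusted p = 0.23) and Ccl2 1.94 (SE 0.66, adjusted p = 0.45), and no gene list passed. Of the 19 STAT5 target genes Bcl6 alone passed on its brightest probe set, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.92, lower in direction, with a median of 0.0652 and a mean of 0.30). The other members gave -1.16 for Myc (SE 0.77), 0.92 for Igf1 (SE 0.62), 0.47 for Socs3, 0.35 for Nox4, -0.28 for Ccnd1 and -0.21 for Bcl2l1. Bcl2l11, Cdkn2b, Mcl1, Cdkn1a, Ccnd2 and Pim1, and the low-group genes Socs1, Il2ra, Igfals and Osm, lay between -0.14 and 0.18.

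Of these 9 calls, 7 remained after quantile normalization and 8 after centring the arrays, and 0 with a replicate block. Socs2 lost its call with a replicate block (adjusted p = 0.17) and without any 1 of the EA arrays, the EA arrays with hormone or the unstimulated YF arrays (0.050 to 0.0963), with differences of 4.93 to 5.29 throughout, and Bcl6 also lost its call in each of these fits and without YF with hormone replicate 1 (0.0639). Bcl6 lost it as well among probe sets above the median level (0.0728), and with the EA numbers of the block crossed both lost it (0.0611 for Socs2 and 0.0677 for Bcl6). The count was 0 with the block and without EA or YF replicate 2, 1 and 3 without EA and YF replicate 1, 48 and 15 without EA with hormone replicate 1 and 2, and 201 without YF with hormone replicate 2.

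Averaged over both mutants, growth hormone raised 61 probe sets and lowered 34, covering 46 and 29 genes, with 3535 at an unadjusted p under 0.05. Of these calls, 12 lay in the low group in every group of arrays. Ccl2 rose by 5.80 (SE 0.33, 4 arrays per side, adjusted p = 0.011), Ccl20 by 5.11 (SE 0.02, adjusted p = 7.3e-07) and Ccl7 by 4.56 (SE 0.13, adjusted p = 0.0021). Cxcl5 (4.27), Cxcl10 (4.07), Cxcl1 (3.95), Cxcl2 (3.14), Bcl3 (3.12), Tnfaip3 (3.11) and Socs2 (2.96) followed, and the Socs2 value averages responses that differed between the mutants, while the brightest Socs2 probe set gave 2.27 (SE 0.24, adjusted p = 0.061) and did not pass. Falls passed in Fos (-3.61, SE 0.20, adjusted p = 0.010), Trib3 (-1.87, SE 0.12, adjusted p = 0.015), Chac1 (-1.63, SE 0.10, adjusted p = 0.013), Hs3st3b1 (-1.43), Oaz3 (-1.10), Slc5a8 (-1.0), Alx1 (-0.83), Egr1 (-0.76), Cnksr3 (-0.70) and Opn1sw (-0.64). Of the genes named on this average, Ccl20, Cxcl10, Cxcl2, Socs2, Hs3st3b1, Oaz3, Slc5a8 and Opn1sw had a side in the low group. Bcl6 averaged -0.90 (SE 0.05, adjusted p = 0.0090), again with different values in the 2 mutants. It was the 1 of 19 STAT5 target genes that passed on its brightest probe set (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.64, higher in direction, with a median of -0.0037 and a mean of 0.14). Cish had a value of 1.10 (SE 0.15, adjusted p = 0.11, with the YF side in the low group), Igf1 0.72, Socs3 -0.37, Bcl2l11 -0.36, Pim1 0.35 and Myc -0.25. Cdkn2b, Nox4, Mcl1, Ccnd1, Ccnd2, Bcl2l1 and Cdkn1a, and the low-group genes Socs1, Il2ra, Igfals and Osm, lay between -0.15 and 0.16.

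Of the 22 cytokine, chemokine and NF-kB target genes, 10 passed higher on this average and 0 lower (15 and 0 adjusted over the list alone), with a camera adjusted p of 1.6e-25 (adjusted p = 0.052 with an estimated correlation). The immediate early list fell with Fos and Egr1 passing lower of 33 (3 higher and 15 lower adjusted over the list alone), at a camera adjusted p of 1.2e-05 (adjusted p = 0.88 with an estimated correlation). For the unfolded protein response list the camera adjusted p was 0.020 in the lower direction (adjusted p = 0.45 with an estimated correlation), with a median of -0.09, a mean of -0.21 and Trib3 and Chac1 passing lower of 20 (0 higher and 2 lower adjusted over the list alone). In YF cells alone this list did not pass (camera adjusted p = 0.70), with 0 members passing in limma and 0 higher and 4 lower at an unadjusted p under 0.05 (0 and 2 adjusted over the list alone). Macrophage and leukocyte, endothelial, epithelial and skeletal muscle markers had no member that passed in limma for the hormone in either mutant. At an unadjusted p under 0.05 there were 0, 1, 0 and 0 of them in EA cells, and 1, 1, 1 and 0 in YF cells. The total of 95 probe sets was 37 with a replicate block, 14 with the 2 treatments as the only factor, 40 and 54 without EA replicate 1 and 2, 39 and 27 without YF replicate 1 and 2, and 373 without YF with hormone replicate 2. The split of 61 higher and 34 lower was 19 and 21 without EA replicate 1, 27 and 27 without EA replicate 2, 20 and 19 without YF replicate 1 and 17 and 10 without YF replicate 2.

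The comparison of EA with YF cells without hormone asks how the 2 cell populations differed before stimulation. H2-DMb2, a chaperone of MHC class II loading, had 12.53 in EA and 2.04 in YF, a difference of 10.49 (SE 0.20, n = 2 per group, adjusted p = 5.3e-05) with the YF side in the low group. The growth factor Igf2 had 14.04 in EA and 6.19 in YF (7.86, SE 0.22, adjusted p = 0.00013). Hif3a (7.34), Nts (7.13), Ptgds (6.37), Krt19 (5.93), Msln (5.75), Htra3 (5.68), Col15a1 (5.67) and Efhd1 (5.61) were also higher in EA, and of these Krt19 alone lay above the low group in YF cells. Lower in EA were Tfap2b, a transcription factor (2.47 against 11.26, a difference of -8.80, SE 0.07, adjusted p = 9e-06), Glipr1 (-7.87), Hoxb5os (-7.40), Tbx4, a T-box factor of the hindlimb (-7.16), Ildr2 (-6.96), Epb41l4a (-6.92), Plac8 (-6.88), Pax1 (-6.68), Slc22a23 (-6.51) and Chdh (-6.45). All of these except Glipr1 lay in the low group in EA cells. The Glipr1 probe sets differed from each other: a second one, with a mean of 10.83, gave 0.01 (SE 0.13, adjusted p = 0.99). In total 4847 probe sets (10.8%) passed, 2483 higher and 2364 lower in EA, and 2271 of them differed at least 2-fold. The count was 2535 and 2707 without EA replicate 1 and 2, and 2603 and 2488 without YF replicate 1 and 2.

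With growth hormone, 4579 probe sets (10.2%) differed between EA and YF cells, 1968 higher and 2611 lower in EA. H2-DMb2 was again highest relative to YF, at 10.22 (SE 0.14, adjusted p = 3.4e-05), followed by Hif3a (7.43), Igf2 (7.15), Msln (6.00), Htra3 (5.65), Col15a1 (5.57), Slurp1 (5.56), Nts (5.53), Efhd1 (5.41) and Crabp1 (5.28). Tfap2b was -8.46 (SE 0.07, adjusted p = 1.1e-05), Tbx4 -7.73, Glipr1 -7.68, Slc22a23 -7.44, Igfbp2 -7.24, Pax1 -7.17, Hoxc5 -7.10, Hoxb5os -7.10, Chdh -6.83 and Plac8 -6.78. Of these genes all except Igf2 and Glipr1 had a side in the low group, and the second Glipr1 probe set gave 0.35 (SE 0.13, adjusted p = 0.18). The comparisons without and with hormone share no arrays but the same estimate of the spread, and 1355 probe sets passed higher in both, 1665 lower in both and 12 in opposite directions. Over all probe sets their differences correlated at 0.811 (Pearson) and 0.388 (Spearman). The count with hormone was 2372 without EA with hormone replicate 2 and 2381 in a fit of the compared arrays alone.

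Averaged over treatments, 7451 probe sets (16.5%) differed between EA and YF cells, 3678 higher and 3773 lower in EA, with H2-DMb2 at 10.31 (SE 0.14, 4 arrays per side, adjusted p = 9.1e-06), Igf2 at 7.50 (SE 0.16, adjusted p = 2.7e-05), Tfap2b at -8.63 (SE 0.05, adjusted p = 1.6e-06) and Tbx4 at -7.45 (SE 0.14, adjusted p = 2.2e-05). Of 46 homeobox and positional genes, which mark the place of origin of fibroblasts along the body, 10 were higher and 16 lower in EA (10 and 22 adjusted over the list alone). The list's camera adjusted p was 0.00049 in the lower direction (adjusted p = 0.13 with an estimated correlation), its median -0.12 and its mean -1.16. After Tbx4, Hoxc5 (-6.65), Hoxc4 (-6.13) and Hoxb4 (-5.21) differed most, and in the other direction Tbx18 (1.95), Tbx5 (1.58) and Hoxa11 (1.26) were among the higher members, named here after their values were seen. Tbx4, Hoxc4, Hoxb4 and Tbx5 had a side in the low group, as had H2-DMb2 and Tfap2b, and Hoxc5 lay there in EA cells with hormone alone (3.33). Among probe sets in the upper quartile of levels the list went the other way without passing (adjusted p = 0.24).

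**Figure D3:**
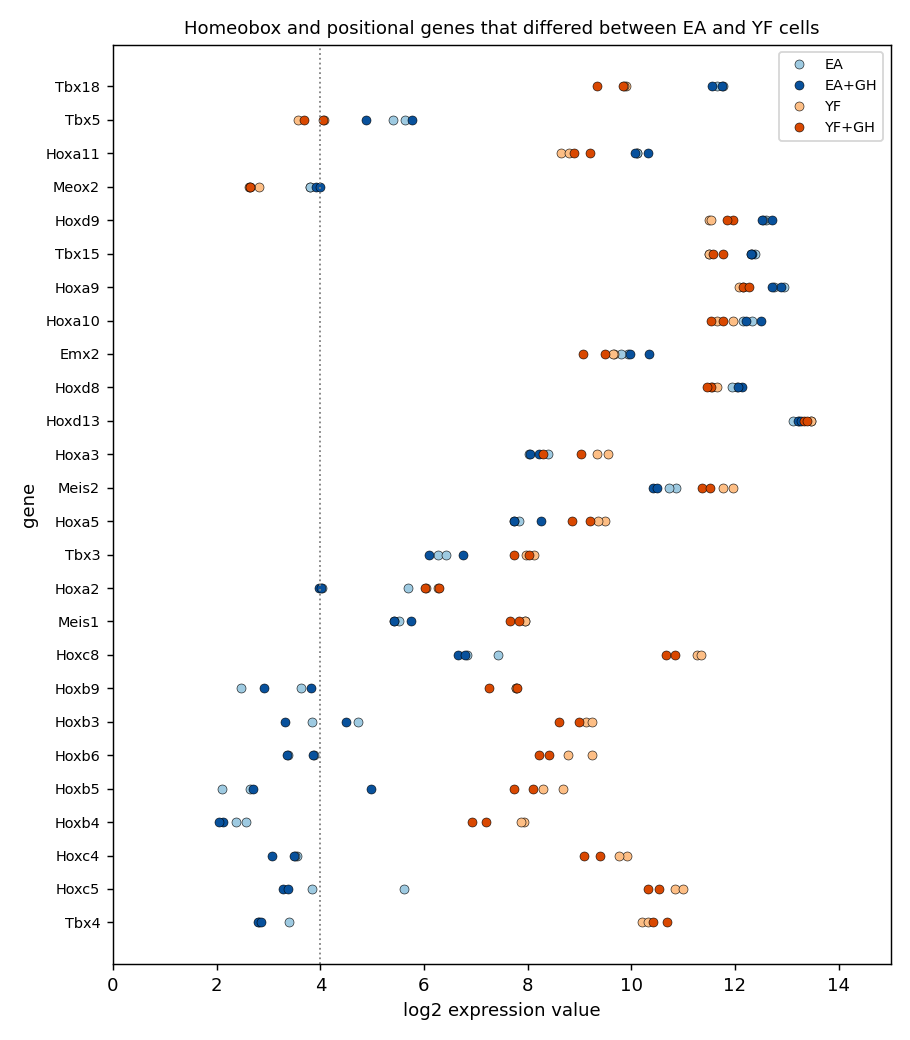
Log2 expression values (horizontal axis) of the 26 homeobox and positional genes that passed between EA and YF cells averaged over treatments (vertical axis, ordered by the difference), where each point is 1 array, colours give the group, and the dotted line at 4 bounds the low group. Tbx4 had means of 3.11 in EA and 10.27 in YF without hormone.

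More genes of the IGF axis, matrix and contractile lists passed lower than higher in EA cells on the same average. The IGF axis list had 3 of 16 members higher and 8 lower (3 and 9 adjusted over the list alone), with a camera adjusted p of 0.0015 (adjusted p = 0.13 with an estimated correlation). Igf2 was higher (7.50), while Igfbp2 (-6.74), Igf1 (-4.70) and Igfbp6 (-3.81) were lower. Of 40 collagen and matrix genes, 5 were higher and 20 lower (7 and 23 adjusted over the list alone), with a camera adjusted p of 4.4e-05 (adjusted p = 0.13 with an estimated correlation). The surface glycoprotein gene Thy1 differed by -4.96 (SE 0.09) and the proteoglycan gene Dcn by -4.45 (SE 0.21), while Mmp9 was higher by 2.92 (SE 0.20). Of 24 TGF-beta target and contractile genes, 1 was higher and 13 lower (1 and 17 adjusted over the list alone), with a camera adjusted p of 1.5e-08 (adjusted p = 0.13 with an estimated correlation). The smooth muscle genes Cnn1 (-4.82, SE 0.19), Myh11 (-4.47, SE 0.14) and Actg2 (-2.66, SE 0.19) differed most. Of the genes in this group of lists, Igfbp2, Dcn and Myh11 had a side in the low group.

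More interferon-stimulated and imprinted genes passed higher than lower in EA cells. Of 25 interferon-stimulated genes, 12 were higher and 0 lower (17 and 1 adjusted over the list alone), with a camera adjusted p of 4.3e-05 (adjusted p = 0.15 with an estimated correlation). Usp18 (3.62, SE 0.29), Ifit1 (3.17, SE 0.28), Oasl2 (3.08, SE 0.41) and Bst2 (2.64, SE 0.19) differed most, with Usp18 and Oasl2 having a side in the low group. Of 21 imprinted genes, 11 were higher and 3 lower (11 and 3 adjusted over the list alone), with a camera adjusted p of 0.013 (adjusted p = 0.33 with an estimated correlation), among them Dlk1, Slc38a4 (2.36) and Cdkn1c (2.15).

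The cell cycle, cholesterol synthesis and heat shock genes that passed were lower in EA cells. For the cell cycle list 0 of 38 were higher and 11 lower (1 and 16 adjusted over the list alone), with a camera adjusted p of 5.6e-07 (adjusted p = 0.17 with an estimated correlation) and small differences, led by Cdc6 (-1.20) and Cdc45 (-0.97). Of 17 cholesterol synthesis genes 0 were higher and 10 lower (0 and 12 adjusted over the list alone), with a camera adjusted p of 1.5e-07 (adjusted p = 0.14 with an estimated correlation), led by Hsd17b7 (-1.0) and Sqle (-0.68). Of 15 heat shock genes 0 were higher and 4 lower (0 and 5 adjusted over the list alone), with a camera adjusted p of 0.0016 (adjusted p = 0.13 with an estimated correlation), and Hspb1 stood out at -3.84 (SE 0.25). The lists named here as differing between EA and YF on average also passed in the same direction without and with hormone taken separately. Without hormone, neural and glial markers passed as well, lower in EA, with 1 of 14 higher (Nes, 1.31) and 2 lower (Stmn2, -2.31, and Sox2, -1.80), 1 and 2 adjusted over the list alone, at a camera adjusted p of 0.048 (adjusted p = 0.41 with an estimated correlation). Over the 7 comparisons 36 of 182 list tests passed with the preset correlation and 0 with an estimated one. The estimate rests on 4 residual degrees of freedom, so the 0 does not show that correlation between genes accounts for the 36 calls. Nor does it uphold them. With fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 57 passed, among them 33 of the 36 in the same direction. The other 3 were the immediate early list in EA cells (fry adjusted p = 0.64), in YF cells (0.11) and averaged over both mutants (0.11).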

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

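All tests of explanations given here were chosen only after the results they concern were seen, while the test of the difference between both hormone responses was fixed before the data were examined.

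For 9 genes the test of the difference found a response to growth hormone that was not the same in EA and YF cells. Socs2 differed by 5.11 on the log2 scale (SE 0.23, adjusted p = 0.025), with 5.51 in EA and 0.40 in YF, on a probe set in the low group in all groups except EA with hormone, while its brightest probe set differed by 5.15 (SE 0.47, adjusted p = 0.10) and did not pass. Bcl6 differed by -1.85 (SE 0.09, adjusted p = 0.025), with -1.82 in EA and 0.02 in YF. Ch25h differed by 1.82 (2.16 in EA, 0.35 in YF) and Ccl20 by 1.44 (5.83 in EA, 4.39 in YF). Dmp1 differed by 0.88, with 0.02 in EA and -0.87 in YF. Elf2 differed by -1.04, Cdca2 by -1.05 and Gda by -1.16, with values of 1.0, 1.02 and 1.17 in YF cells and of -0.04, -0.03 and 0.01 in EA cells. Opn1sw differed by -1.17, with -1.22 in EA and -0.05 in YF. Brighter probe sets of Dmp1, Gda, Cdca2 and Elf2 gave -0.57, -0.21, -0.76 and 0.07 and did not pass. Apart from Ch25h, Elf2 and Bcl6, these genes had a side in the low group. Dmp1, Gda and Opn1sw lay there in every group, so their calls concern values inside the low group only.

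Socs2 and Bcl6 had a hormone response in EA cells and values near 0 in YF cells. Less receptor RNA in YF cells is argued against by Ghr, which was lower in EA than in YF (-0.27, 95% interval -0.38 to -0.16). Less STAT5 mutant RNA in YF cells stays open: the brightest Stat5a probe set gave -2.79 for EA minus YF (95% interval -3.59 to -1.98), but the other one lay in the low group, and whether either detects the introduced construct was not analysed here. That the mutation itself accounts for the difference is a candidate explanation that cannot be told apart from other differences of the cell populations, since 10.8% of probe sets differed between them without hormone. Both calls also end with a replicate block (adjusted p = 0.17), with differences of the same size.

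Of 22 chemokine and NF-kB target genes 7 passed higher with hormone in EA and 5 in YF cells, and the list's camera calls were lost with an estimated correlation (adjusted p = 0.050 in EA and 0.24 in YF). The route that raises Socs2 in EA cells is argued against as the only cause, because the list's median change in YF cells was 1.15 while the brightest Socs2 probe set there had -0.30 (95% interval -1.15 to 0.55), against 4.84 in EA. A part of that route in EA cells is not excluded. In the difference of the responses, 7 of the 22 members were higher and 1 lower in EA at an unadjusted limma p under 0.05. Leukocytes in the treated cultures stay open, because 12 of their 15 markers lay in the low group and set the median's bootstrap upper bound of 0.142, while the 3 above it, Cd68 (change 0.19, SE 0.15), Csf1r (0.47, SE 0.18) and Cd14 (0.29, SE 0.23), had values above 0 that did not pass. A contaminant of the hormone preparation acting through Toll-like receptors cannot be told apart from the hormone, since hormone and preparation always came together, and interferon-stimulated genes without Cxcl10 and Irf1 had a camera p of 0.038 in the lower direction in EA cells and of 0.25 in the higher direction in YF cells. Signalling by the hormone that does not pass through STAT5 stays open as well, as untested.

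EA and YF cells differed at many probe sets. Growth hormone acting through the mutants is argued against as the cause, since 4847 probe sets differed without hormone. Array scaling is not decided here. Quantile normalization kept 6842 of the 7451 averaged calls. The deposited arrays already had near-equal distributions, with 75th percentiles of 9.04 to 9.14, so this is a weak test of scaling. Different positional identity of the fibroblast populations is a candidate explanation that stays open. Among genes above the low group, 17 of 31 positional genes (54.8%) passed and differed at least 2-fold, against 1212 of 10748 others (11.3%), an odds ratio of 9.55 (95% interval 4.42 to 21, Fisher's exact p = 4.6e-09, two-sided, with genes taken as independent, which they are not), but this count restates the differences of the same list that raised the explanation and does not support it further. The mutation stays open too, as each mutant was measured in a single infected population or set of populations whose origin the labels do not give.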

How the results depend on the processing

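The crossed pairing of replicate numbers was chosen only after the data were seen, and every other alternative here was fixed beforehand. Where a cause is not named, the cause was not tested.

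Counts of probe sets are given for hormone in EA (61), hormone in YF (81), the difference of both (9), EA against YF without hormone (4847), with hormone (4579), hormone averaged (95) and EA against YF averaged (7451), and counts within 1.5 times of these are left out. Quantile normalization gave 37 for hormone in EA and 53 in YF. Under it 34, 46, 7, 4277, 4029, 63 and 6842 of the calls remained, in the order above. The difference then had 5 higher and 3 lower, against 4 and 5. Centring arrays on their medians split hormone in EA as 23 higher and 22 lower, against 42 and 19. The filter to probe sets above the median level gave 1 for the difference. The upper-quartile filter, which tests fewer probe sets, gave 27, 29, 1, 3175, 37 and 4562 for hormone in EA, in YF, the difference, EA against YF without hormone, hormone averaged and EA against YF averaged. The eBayes fit with trend and robust gave 106, 187, 42 and 157 for hormone in EA, in YF, the difference and hormone averaged. A fit of the compared arrays alone, with fewer arrays, gave 4 for hormone in EA, 1 in YF and 2381 for EA against YF with hormone. With the treatments as the only factor, the averaged hormone effect had 14.

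Leaving out 1 array at a time gave 9 to 80 for hormone in EA, 8 to 675 in YF, 0 to 201 for the difference, 2488 to 5170 and 2372 to 4939 for EA against YF without and with hormone, 27 to 373 for hormone averaged and 5470 to 7763 for EA against YF averaged. A group left with 1 array was assumed to vary like the other groups. The highest hormone counts in YF, in the difference and on average came without YF with hormone replicate 2.

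The replicate block gave 15 for hormone in EA, 21 in YF, 0 for the difference by limma (4385 at an unadjusted p under 0.05 without the block) and 37 for hormone averaged. Replicate differences of the groups correlated at -0.21 (EA, EA with hormone), -0.062 (EA, YF) and 0.0021 (EA with hormone, YF). The other pairs of groups gave -0.30 (EA, YF with hormone), 0.37 (both groups with hormone) and 0.12 (YF, YF with hormone). These values do not decide whether arrays of different groups share a component. The numbers were not taken as pairs because no label ties a number to a shared culture or day. With the EA numbers crossed the block gave 131 for hormone in YF and 2 for the difference.

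The 16 probe sets higher with hormone in both mutants became 9 with centring, 10 with the upper-quartile filter, 27 with trend and robust, 8 with the replicate block and 3 to 12 without 1 array. The 36 gene list calls became 0 with an estimated correlation, 28 to 43 otherwise and 31 to 39 without 1 array. The homeobox list turned to the higher direction under the upper-quartile filter without passing, at adjusted p of 0.19 without hormone, 0.16 with it and 0.24 averaged. Stat5a, EA minus YF, ran from -3.36 to -3.04 without 1 array and kept its call in every alternative run, and it was not among the upper-quartile probe sets. Of calls on named genes, 90 were lost in the fit of the compared arrays alone (151 kept), 62 with the replicate block (317 kept), 33 with centring (346 kept), 32 with quantile normalization (347 kept), 27 with the crossed block (352 kept), 14 with trend and robust (365 kept), 10 with the median filter (360 kept), 0 with the upper-quartile filter (133 kept) and 711 of all those refitted without 1 array (2321 kept), and 0 changed direction. A filter retested only the calls whose probe sets it left in, so the 0 lost with the upper-quartile filter says nothing of those removed. The fit of the compared arrays alone covered only the contrasts between single groups. The planned change of pseudocount was not run, as the values are on the log2 scale. Signal limits the folds that have a side in the low group, below 4, and their SE and p may be too small.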

Other observations

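The tests of a wider set of NF-kB targets and of ATF4 targets were set down before their results were seen, although several ATF4 targets also stand in lists already examined. The ATF4 tests of the difference and by bootstrap, the fits of both sets without 1 array and the counts of other splits were chosen after.

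Several groups that did not pass as lists held single genes with large differences between EA and YF cells averaged over treatments. Col2a1, a cartilage collagen, differed by -5.40 (SE 0.12, adjusted p = 3e-05) and Comp by -1.39, while Sox9 was higher by 0.46, with 1 of 13 chondrocyte and osteoblast markers higher and 4 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.29 in the lower direction, mean -0.61, median 0.04). The keratins Krt19 (5.20) and Krt7 (3.01) were higher in EA, with 3 of 13 epithelial markers higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.29). The troponin gene Tnnt3 was higher by 5.21 (SE 0.22) and Tnnt2 by 1.35, while Acta1 differed by -1.96 and Tnnc1 by -0.64, with 2 of 16 muscle markers higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.54). Flt1 (-4.04, SE 0.32) and Tek (-1.58) were the 2 of 13 endothelial markers that passed, both lower (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.15). Cd68, a lysosomal protein of macrophages, was higher by 3.15 and Cd53 lower at -1.42, the 2 of 15 leukocyte markers that passed (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.77). Col2a1, Tnnt3, Flt1 and Cd53 had a side in the low group.

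Of 21 oxidative stress genes 8 were higher and 4 lower in EA (9 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.36). Gsta2 (3.53, SE 0.38), Slc7a11 (2.03, SE 0.32) and Gstm2 (1.62, SE 0.06) were higher in EA, and Gpx3 was lower (-3.29, SE 0.11), with Gsta2 and Slc7a11 having a side in the low group. Among p53 pathway genes Fas was higher (0.75) and Perp (-0.95) and Pmaip1 (-0.92) lower, with 3 of 18 higher and 4 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.92).

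A wider NF-kB response to the treatment was tested on 18 further target genes outside the fixed list. As a list they were higher with hormone in YF cells (camera p = 3e-07, p = 0.0052 with an estimated correlation, median 0.46). They were also higher in EA cells (camera p = 1.4e-10, p = 0.0023 with an estimated correlation, median 0.29). Without 1 array the median was 0.26 to 0.36 in EA and 0.46 to 0.63 in YF cells. Unadjusted in the same way, the fixed cytokine, chemokine and NF-kB list had similar values. Its camera p with an estimated correlation was 0.0019 in EA and 0.0092 in YF cells. Of the 18 genes 1 passed in each mutant, Casp4 in EA cells (2.83, adjusted p = 0.046) and Cx3cl1 in YF cells (1.49, adjusted p = 0.048). At an unadjusted p under 0.05 there were 8 higher and 0 lower in EA cells and 10 higher and 1 lower in YF cells, and some members had values below 0, such as Rel (-0.24) and Irak3 (-0.10) in EA and Cd40 (-0.09) in YF. This is consistent with a response that extends beyond the listed chemokines, as a hypothesis.

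The falls of Trib3 and Chac1 led to a test of 24 other ATF4 target genes. In EA cells the list was lower (camera p = 2.4e-07, p = 0.012 with an estimated correlation, median -0.16, bootstrap interval -0.32 to -0.06), with 0 of 24 passing in limma and 0 higher and 8 lower at an unadjusted p under 0.05. In YF cells it was higher (camera p = 0.00064, p = 0.044 with an estimated correlation, median 0.13, bootstrap interval 0.02 to 0.26), with 0 passing in limma and 6 higher and 0 lower at an unadjusted p under 0.05. The difference of the responses was lower in EA (camera p = 2.6e-07, p = 0.012 with an estimated correlation, median -0.27). A fall of ATF4 targets along with Trib3 was thus not seen in YF cells, where the median was 0.13 to 0.19 without 1 array. The lower bound there was -0.02 without YF replicate 1 or YF with hormone replicate 2, so a fall is not excluded. In EA cells a fall stays open, as the values that raise it were already seen. Averaging the mutants gave a camera p of 0.51 and a median of -0.01, which joins opposite directions and decides nothing. The bootstrap draws genes as if they were independent, which they are not, and it does not measure the spread between arrays. The median in EA cells was -0.08 without EA with hormone replicate 2, -0.31 without EA with hormone replicate 1 and -0.24 without EA replicate 1. Without 1 array the p with an estimated correlation ran from 0.012 to 0.055 in EA, with 0.055 without either YF array with hormone. It ran from 0.030 to 0.20 in YF, where it stayed under 0.05 only without either EA array with hormone, and from 0.011 to 0.088 for the difference, with 0.088 without YF with hormone replicate 2.

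The 8 arrays were divided into 4 and 4 in all 35 ways. For the averaged hormone effect the real division gave 14 probe sets and 2 of the 35 divisions gave as many, the other being EA against YF with 6523. The EA against YF division is always among the 35, so this count could not have excluded chance and decides nothing. The EA against YF division points to the structure of the samples, and the highest count apart from both design divisions was 2. For EA against YF the real division gave 6523, 1 of 35 divisions gave as many, and the highest other was 14. That is the smallest share that 35 divisions allow, and the arrays of 1 mutant may share a cell population. The count shows that arrays of the same mutant resemble each other. It does not exclude chance differences between populations.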
